A study of Homo sapiens with 277 samples.

How the data were processed

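RNA was measured by GeoMx digital spatial profiling, in which probes carrying a sequence tag are hybridised to a tissue section, released by light from a chosen region and sequenced. Thin sections of formalin-fixed, paraffin-embedded human brain were used, per the labels. The deposited values are deduplicated counts per probe: each file lists probe identifiers with the number of distinct molecular identifiers counted for them. Per the file headers, reads were processed with DRAGEN GeoMx 3.8.4-96, with a tag of 12 bases matched with at most 1 edit and a molecular identifier of 14 bases. The submitters' processing notes name the build hg38, although probe counting by tag uses no genome coordinates. How regions were outlined beyond the staining, and the identity of the negative-control probes, are not given in the sources used here.

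The series held 277 files, of which 274 were captured regions and 3 were no-template controls, 1 for each of 3 plates (called A, B and C here). Stage, region type, donor number and region number were taken from the sample titles and the plate from the library names. No pair of files held identical counts. The files do not pair probe identifiers with gene names and the reference table lists none of these identifiers. Gene lists fixed before the data were examined were therefore not run, and neither was subtraction of the negative-control probes. Without gene names the X-inactive and Y-linked transcripts could not be set aside, so probe identifiers are printed only for comparisons within donors, and none for comparisons between stages.

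Regions were left out with under 1000 raw reads, under 80% trimmed and stitched or under 75% aligned reads, a saturation under 50% or under 1000 counts, limits set before the data were examined. These limits removed 2 regions, 1 Low AD white matter plaque region with 0 raw reads and 1 High AD sparse plaque region with 876 counts. In the 272 kept regions 87.9% to 95.2% of reads aligned and saturation was 91.7% to 99.4%, so that deeper sequencing of the same libraries would add few molecules. The 10 most abundant probes held 3.96% of all counts and the most abundant 1.94%.

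Counts were summed over the kept regions of each donor and region type, since the donor is the replicate. Sums ranged from 17490 to 1521702 counts. Probes were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold in each of 14 comparisons. Comparisons between region types used the donors holding both types, with the donor as a block. Deviations from the group mean over the 500 most abundant probes correlated between region types of a donor at 0.149 or higher in every pair, with medians from 0.612 to 0.833, which bears out the pairing by donor. Stages were compared in 1 fit per region type, without a block, because a donor belongs to 1 stage. Fold changes are log2 ratios of the fit; the differences printed with an SD are means over donors of differences in log2 CPM with a prior count of 2. Intervals of fold changes are 95% intervals from the F statistic and its degrees of freedom. Counts per region were compared through donor medians with exact sign-flip tests within donors and exact permutation tests between stages, all two-sided, adjusted over 13 comparisons.

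The rule for named probes, set before the data were examined, took past-threshold probes with the same sign in at least 3 of 4 pairs by size of fold change, and it was limited to 2 rising and 2 falling probes because the identifiers carry no names. For comparisons with 2 calls that fell outside the rule the probes were named after their values were seen. The procedure was tested on counts simulated from the real profiles with 200 probes changed 1.5-, 2- or 3-fold in each comparison. Among changes of 2-fold, 98.5% were recovered in white against grey matter, 98.5% and 97% in dense and sparse plaque against grey matter, 97% in dense against sparse plaque and 91% in white matter plaque against white matter. Between stages the share was 2.99%, 26.9% and 5.97% in grey matter (High AD with Control, Low AD with Control, High AD with Low AD), 52.2%, 41.8% and 32.8% in white matter, 25.4% in dense and 19.4% in sparse plaque, and 2.99% for the interaction. At most 10 unchanged probes were called in any simulated comparison. The counts were drawn independently for each probe from the fitted model, so variation between donors that probes share was absent from the simulated stage comparisons. Regrouping the real donors gave up to 224 calls in High AD against Low AD white matter. The simulated shares therefore need not hold for the real comparisons between stages.

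Alternatives listed before the data were examined were upper-quartile scaling, DESeq2 1.42.0, no filter and a stricter filter on low counts, all regions kept, regions under 10000 counts left out (22 of those kept), the fit without or with a block of donor number, plate as a block, single regions in limma 3.58.1 with the donor as a random block, thinning to the lowest summed total, and leaving out each donor. Added after the data had been seen were a limit on single regions (the highest region of a probe held to 3 times the rate of the others, or 5 counts) and leaving out the 20 most abundant probes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.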

Results

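The data describe archived, formalin-fixed human brain in which oligodendrocyte lineage cells (stained for the transcription factor Olig2) and amyloid plaques (stained for beta-amyloid) guided the choice of small tissue regions for spatial transcriptome profiling. The regions came from 12 donors in 3 stages of 4 donors each, which the labels call Control, Low AD and High AD. The design text speaks of normal ageing, preclinical disease and Alzheimer's disease told apart by Braak score, a staging of tau pathology, and does not say how these match the labelled stages. The 5 region types were grey matter without plaque, white matter without plaque, sparse plaque, dense plaque and white matter plaque. Of 274 captured regions, 272 entered the comparisons: 72 of grey matter without plaque, 69 of white matter without plaque, 72 of dense plaque, 42 of sparse plaque and 17 of white matter plaque. Only 2 control donors had dense or sparse plaque regions, and 1 Low AD donor had no region of white matter without plaque. The RNA of each region was counted with 18815 indexed probes, which the files list by probe identifier without a gene name. The comparisons below are therefore given per region type and stage, by numbers and sizes of probe changes, and no gene or pathway is named.

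The kept regions held between 3514 and 191499 deduplicated counts, with a median of 33477, and a probe had a median of 2.05 counts per region. Only 99 probes averaged 10 or more counts per region, so that single regions carried little information per probe and counts were summed over the regions of each donor and region type. White matter yielded more counts than grey matter. The median count per region of a donor was 2.26-fold higher in white than in grey matter without plaque and was higher in 11 of 11 donors (exact sign-flip test, two-sided, p = 0.000977, adjusted p = 0.0127 over 13 depth comparisons). In the other 12 depth comparisons, between plaque and plaque-free regions and between stages, the adjusted p was 0.531 or higher (exact tests). The stage tests had few donors a side and could hardly pass after adjustment, so a depth difference between stages is not excluded. Low AD regions held 1.73-fold the counts of Control regions in grey and 1.66-fold in white matter without plaque. High AD regions held 0.81 and 0.90 of the Control counts and 0.47 and 0.54 of the Low AD counts. The 3 no-template wells held 23, 10 and 1 counts.

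**Figure D1:**
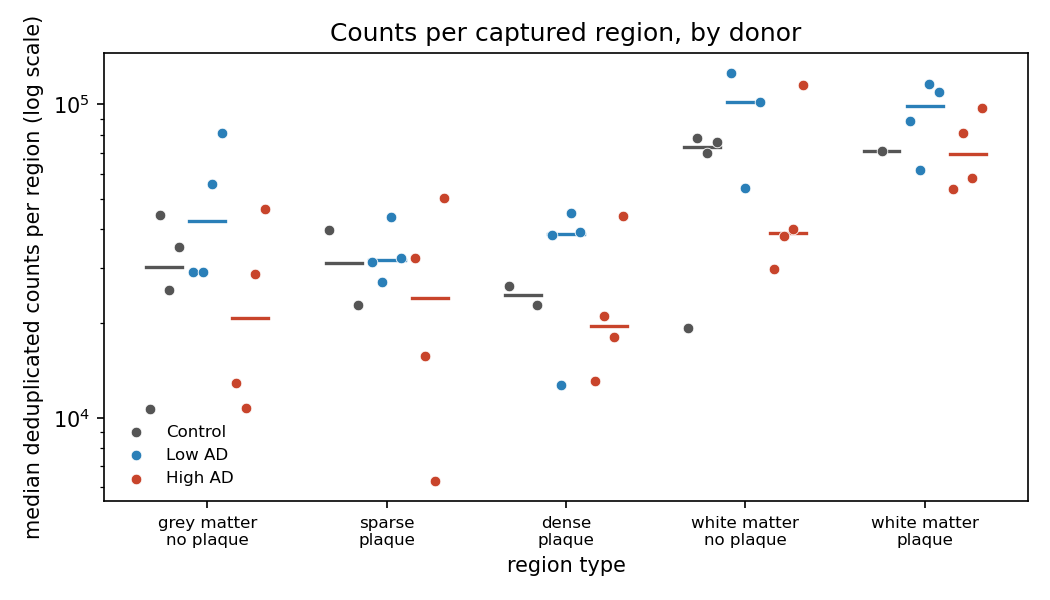
Median deduplicated counts per captured region (log axis) for each donor, by region type and stage; each point is a donor and each bar the median of the donors. White matter regions lie above grey matter regions, 2.26-fold on average in the 11 donors with both types without plaque.

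The first comparison asked how white matter differed from grey matter away from plaques, within the same donors. In white matter, 54 probes were higher and 170 were lower than in grey matter, of 6454 tested in 11 donors (edgeR quasi-likelihood test with the donor as a block, adjusted p under 0.05). Most changes in counts, with background included, were small. The probes higher in white matter had a median log2 fold change of 0.67 (1.59-fold), with 3 probes above 2-fold, and the probes lower in white matter had a median of -0.73 (1.66-fold), with 32 beyond 2-fold. The largest rise was that of probe RTS0027108, by 1.35 ± 0.45 on the log2 scale (mean ± SD of the donors' differences, n = 11), from a mean of 2675 CPM (counts scaled to a common library size) in grey matter to 6569 in white matter (adjusted p = 4.28e-11). Probe RTS0026729 rose by 1.16 ± 0.46, from 815 to 1763 CPM (adjusted p = 4.85e-09). Probe RTS0030851 fell from 492 CPM in grey matter to 134 in white matter, a difference of -1.76 ± 0.66 (fitted log2 fold change -1.87, adjusted p = 9.95e-12). Probe RTS0051177 fell from 333 to 91.9, a difference of -1.72 ± 0.85 (fitted -1.85, adjusted p = 2.35e-09). The adjusted p values are those of the fitted fold changes, not of the means over donors. Each of these 4 probes changed the same way in 11 of 11 donors, and 56 of the 224 called probes did so. The mean difference had the sign of the fit for 224 of the called probes in the Control donors, 220 in the Low AD donors and 219 in the High AD donors. Within plates the same held for 210 on plate A and for 224 on each of plates B and C. The probes were chosen in these same donors, so high shares follow in part from the selection and are no independent check. The balance between directions depended on the scaling and on the unit of the fit. With upper-quartile scaling, which moved the median of all probes to 0.09, 107 probes were higher and 121 lower in white matter. With single regions as the unit, also scaled by TMM, the median of all probes was 0.13, and 371 were higher and 71 lower. In the main fit that median was 0.007. Without the donor as a block 58 probes passed, and 20 of 171 tested passed after each summed profile was thinned to the lowest total.

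**Figure D2:**
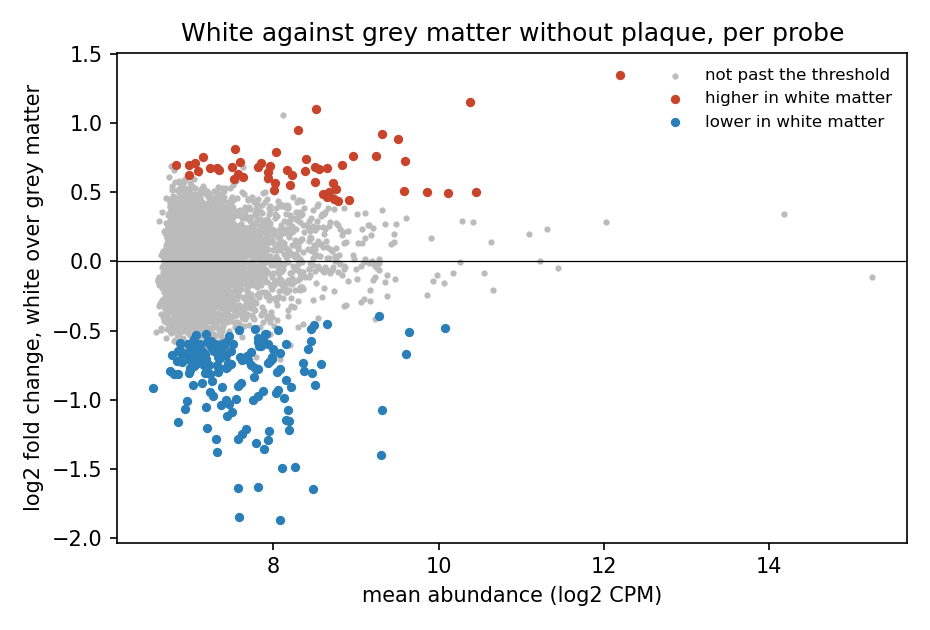
Log2 fold change of white over grey matter without plaque for each of 6454 tested probes, against mean abundance in log2 CPM, from 11 donors. The 54 probes called higher in white matter are in red and the 170 called lower in blue; grey points did not pass the threshold.

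Whether the white to grey matter difference itself changed with stage was tested with an interaction term. No probe passed between High AD and Control (302 at an unadjusted p under 0.05 of 6454, edgeR), between Low AD and Control (288) or between High AD and Low AD (311). The size of change that this test could detect was not measured, so a difference between stages is not excluded.

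The next comparisons asked what distinguished grey matter with plaque from grey matter without it in the same donors. Dense plaque regions did not differ from grey matter without plaque in any of 3904 tested probes in 10 donors (edgeR, 0 calls; 253 at an unadjusted p under 0.05; 0 calls with DESeq2). Without a filter on low counts, and with single regions as the unit, 2 probes passed in each case, lower in dense plaque. For the tested probes the precision limited the size of a change in counts. The 95% interval of the fold change lay within 2-fold for 99.1% of them and extended 0.39 on the log2 scale to either side for the median probe. Background was not subtracted, so these intervals do not limit the change in the RNA itself, and probes that failed the filter are not covered. In counts simulated from the same profiles, 98.5% of 2-fold changes and 32.8% of 1.5-fold changes were recovered. In this comparison the probes called higher in white than in grey matter had a median log2 fold change of -0.14, and those called lower in white matter had a median of 0.10. These probes were chosen with the same grey matter profiles, and whether the medians differ from 0 was not tested.

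Sparse plaque regions gave the same count. None of 1443 tested probes differed from grey matter without plaque in 10 donors (edgeR, 0 calls; 46 at an unadjusted p under 0.05; 0 with DESeq2), although 19 passed without a filter on low counts, 2 higher and 17 lower. In the filtered test the 95% interval of the fold change extended 0.37 on the log2 scale to either side for the median probe. The probes called higher in white than in grey matter had a median log2 fold change of 0.04 here, and those called lower a median of 0.005.

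Dense and sparse plaque regions differed in 2 of 2509 tested probes in 10 donors (148 at an unadjusted p under 0.05). Both lay outside the rule for named probes because their sign was not shared widely enough, and they are given because the count was so low. Probe RTS0051559 was higher in dense plaque (edgeR fitted log2 fold change 0.98, adjusted p = 0.0408) in 6 of 10 donors. Its mean difference over donors was 0.59 ± 1.04 (SD, n = 10). Probe RTS0028255 was lower (edgeR fitted log2 fold change -0.78, adjusted p = 0.0355) in 7 of 10, with a mean difference of -0.46 ± 1.27 (n = 10). The spread between donors exceeded both means. DESeq2, upper-quartile scaling, thinning, the unblocked fit and single regions as the unit gave 0 calls each.

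In white matter, plaque regions were compared with plaque-free regions of 8 donors. Of 5150 tested probes, 2 differed (262 at an unadjusted p under 0.05), again outside the rule for named probes. Probe RTS0030334 was higher in white matter plaque (edgeR fitted log2 fold change 1.29, adjusted p = 0.0377) in 5 of 8 donors. Its mean difference over donors was 0.56 ± 1.30 (SD, n = 8), and 34.5% of its counts came from a single region. Probe RTS0026823 was lower (edgeR fitted log2 fold change -1.61, adjusted p = 0.0207) in 5 of 8 donors. Its mean difference was -1.06 ± 1.74 (n = 8), and 51.2% of its 467 counts came from a single region. The spread between donors exceeded both mean differences. DESeq2 gave 0 calls. For 99.3% of the tested probes the 95% interval lay within 2-fold, for counts with background included.

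The remaining comparisons asked how the same region type differed between stages, with the donor as the unit. Grey matter without plaque differed in 3 of 6328 tested probes between High AD and Control donors (2 higher and 1 lower in High AD, n = 4 and 4; 628 at an unadjusted p under 0.05; 0 calls with DESeq2; 2 higher and 2 lower with upper-quartile scaling). A plate block gave 3 calls, of which 1 was among these. The count rested on single donors, since it was 10 without Control donor 1 or 4, 7 without Control donor 3, 25 without High AD donor 2, 38 without High AD donor 3 and 31 without High AD donor 4. Between Low AD and Control donors 23 probes differed, 10 higher and 13 lower in Low AD (n = 4 and 4; 919 at an unadjusted p under 0.05), and DESeq2 called 174, of which 11 were among the 23. The balance of directions was not stable: DESeq2 gave 133 higher and 41 lower, thinning gave 0 higher and 11 lower, and the fit without Low AD donor 1 gave 5 higher and 0 lower. With plate as a block 11 of these 23 still passed and no others. The count was 154 without Control donor 1, 11 without Control donor 3, 13 without Control donor 4, 5 without Low AD donor 1 and 9 without Low AD donor 3. High AD and Low AD grey matter did not differ in any tested probe (edgeR, 0 calls; 392 at an unadjusted p under 0.05; 0 with DESeq2). In the fit with plate as a block 6 probes passed, all higher in High AD, and 2, 21, 39 and 32 probes passed in the fit with no block without High AD donor 1, 2, 3 and 4. Precision was lower than within donors: the 95% interval lay within 2-fold for 31.7% of probes between High AD and Control, 50.9% between Low AD and Control and 40.1% between High AD and Low AD.

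White matter without plaque was tested in the same way, with 18753 of the 18815 probes passing the filter, against 6328 in grey matter. The filter thus removed few probes, and the negative-control probes, which are not identified, may be among those tested. Between Low AD and Control donors 661 of 18753 tested probes differed (n = 3 and 4; 3278 at an unadjusted p under 0.05), with 435 higher in Low AD by a median of 1.24 on the log2 scale and 226 lower by a median size of 1.11. The called probes had a median abundance of 6.26 log2 CPM (higher) and 5.26 (lower), and how far these lie above background is not known. As many calls came from 2 of 35 splits of these donors between the stages, the real one included. DESeq2 called 436 (415 higher and 21 lower). Upper-quartile scaling called 348 higher and 277 lower, and 562 of these were among the 661. With plate as a block 9 probes passed, 8 of them among the 661, although all 661 kept their sign and their median size was 1.11 against 1.18 without the block; the same fit called 11 in grey matter. Within plate A, which held 2 Low AD donors and 1 Control donor, 594 of the 661 had the sign of the whole comparison, and within plate B, with 1 donor of each, 658 did; plate C held no Low AD region of this type. These shares are high in part because the 661 were chosen in the same donors, and plate B sets 1 donor against 1. The count was 1022 without Control donor 1, 195 without Control donor 2, 236 without Control donor 3, 179 without Control donor 4, 200 without Low AD donor 1 and 308 without Low AD donor 3. Of the 23 probes called in grey matter of Low AD against Control donors, 20 had the same sign in white matter and 10 were also called there; both comparisons used the same donors and are not independent.

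High AD and Control white matter differed in 1 of 18753 tested probes, which was lower in High AD (n = 4 and 4; 2567 at an unadjusted p under 0.05), whereas DESeq2 called 209 (204 higher and 5 lower). The edgeR fit with a plate block gave 0 calls. The edgeR count was 199 without Control donor 1, 0 without Control donor 2, 3 or 4 or High AD donor 2, and 13, 17 and 22 without High AD donor 1, 3 and 4. High AD and Low AD white matter also differed in 1 probe, lower in High AD (n = 4 and 3; 1192 at an unadjusted p under 0.05; 0 with DESeq2). When plate was a block that probe no longer passed, and 1 other probe did. The count without a block was 64 without Low AD donor 2, 24 without High AD donor 3, 7 without High AD donor 4 and 0 without any of High AD donors 1 and 2 and Low AD donors 1 and 3. The difference between Low AD against Control and High AD against Control is the comparison of High AD with Low AD, so the larger count in Low AD is not shown to differ from that in High AD.

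**Figure D3:**
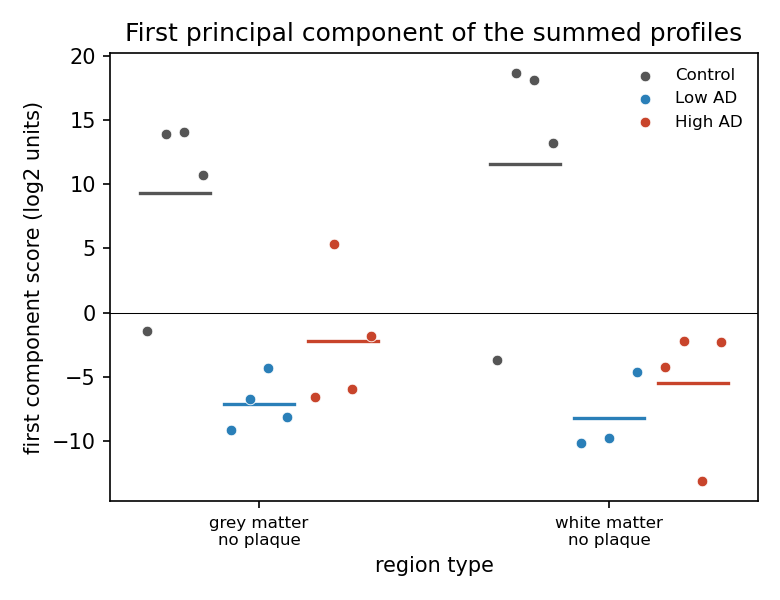
Score of each donor on the first principal component of log2 CPM (500 most abundant probes), fitted separately to grey matter (38.0% of the variance) and white matter (53.1%) without plaque; points are donors and bars are stage means. Control donors average 9.32 in grey and 11.59 in white matter, with Control donor 1 below 0 in each. The sign of each component is arbitrary and was set so that the Control scores sum above 0.

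Plaque regions were compared between disease stages as well. Dense plaque regions of High AD and Low AD donors did not differ in any of 10864 tested probes (n = 4 and 4; edgeR, 0 calls; 915 at an unadjusted p under 0.05), and DESeq2 called 22. A block for plate gave 1 call. Leaving out High AD donors 1, 2 and 3 gave 13, 5 and 9 calls, and leaving out Low AD donor 3 gave 1. Sparse plaque regions did not differ in any of 1879 tested probes (n = 4 and 4; edgeR, 0 calls; 120 at an unadjusted p under 0.05; 0 with DESeq2), with 1 call without Low AD donor 2. The 95% interval lay within 2-fold for 68.0% of probes in dense plaque and 35.9% in sparse plaque, and simulated 2-fold changes were recovered in 25.4% and 19.4% of cases. A difference of that size between stages was therefore often not detectable at this depth and number of donors.

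The last comparison asked whether the change from grey matter without plaque to dense plaque differed between High AD and Low AD donors. The interaction passed for 7 of 7528 tested probes, 1 with a higher and 6 with a lower change in High AD (n = 4 and 4; 417 at an unadjusted p under 0.05). DESeq2, the unblocked fit and single regions as the unit gave 0 calls, and upper-quartile scaling gave 1 higher and 2 lower. The count was 0 without Low AD donor 3 or 4, 1 without Low AD donor 1, 11 without Low AD donor 2 and 15, 17, 36 and 27 without High AD donors 1, 2, 3 and 4.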

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

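The tests of plate, scaling and depth in this part were chosen after the result they bear on had been seen, and the flags are from fixed rules. In 19 groups of donors tested for a value far from the rest, 3 held one, and chance alone gives about 1 in 20 groups. In Low AD dense plaque the lowest donor had a median of 12720 counts per region, against a median of 38682 over the group. In Control white matter without plaque the lowest donor, Control donor 1, had 19352, against 72984. In High AD white matter plaque, High AD donor 1 scored -0.15 on the axis described in the last paragraph of this part, against 0.73 to 0.89 in the other donors. The score is a share of each donor's own distance between grey and white matter. That distance was 0.51 in log2 units in this donor and 0.83 to 2.28 in the other High AD donors. The low score may therefore come from the small distance, and plain log2 units were not tested for a donor far from the rest. The no-template wells of plates A and B held 23 and 10 counts, above the limit of 3 that a count of 0 allows, and the shallowest kept region held 3514. The change from grey matter to dense plaque differed between High AD and Low AD in 7 probes by an interaction test.

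Other splits of the donors were run for each comparison to see whether chance could be excluded as the source of its calls. For white against grey matter only the real split of 100 gave 224 calls and the highest other gave 45, which argues against chance. A share of 1 in 100 is the smallest that the splits run can give, and it was not adjusted over the 14 comparisons. For Low AD against Control in grey matter 1 of 35 splits, the real one, gave as many as 23 and the highest other gave 6. For the interaction 1 of 35 gave as many as 7, with 5 in the highest other, and DESeq2, thinning, the limit on single regions and the fits without Low AD donor 3 or 4 gave 0 calls. That share is the smallest that 35 splits can give and was not adjusted over the 14 comparisons, so chance is not firmly excluded for either, least of all for the interaction. Chance was not excluded in the other comparisons that had calls. Dense against sparse plaque had 2 calls, reached by 5 of 100 splits (highest other 2), and white matter plaque had 2, reached by 37 of 100 (highest other 4). In grey matter, 6 of 35 splits reached the 3 calls of High AD against Control (highest other 15). In white matter, 10 of 35 splits reached the 1 call of High AD against Control (highest other 58) and 24 of 35 the 1 call of High AD against Low AD (highest other 224). Where the real count was 0, all splits reach it by construction and the comparison has no calls to explain. This holds for dense and sparse plaque against grey matter (100 splits each, at most 4 and 3 calls in another split) and for High AD against Low AD in grey matter, dense plaque and sparse plaque (35 splits each, at most 63, 77 and 114). Some splits called many times the real number, and what the donors grouped by them share was not tested.

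The 661 calls between Low AD and Control white matter were reached by 2 of 35 splits, and the highest other split gave 1016, with Control donor 1 grouped with the Low AD donors. The median size of the called probes' log2 fold change was 0.943 of its size once plate was a term (1.11 against 1.18). Of the 661, 649 kept at least 0.5 of theirs, which argues only weakly against plate as the whole cause. The 661 were chosen in these same donors without the plate term, so high shares follow in part from the selection. The calls fell to 9; the median standard error of the 661 was 0.30 before and 0.40 after, with 8 and 6 residual degrees of freedom, and which of these changes ended the calls was not tested. A different share of background counts could not be excluded: fold change followed abundance with an absolute Spearman rho of 0.414 across probes, which are not independent replicates, but other splits reached 0.477. Peculiarities of the Control donors would show alike in both disease stages. In grey matter the Low AD donor absent from the white matter comparison had the same sign in 88.1% of 345 probes. The High AD donors had it in 68.1% to 77.7%, so the margin of 10 points set beforehand against this explanation was passed. The Low AD donor was also the deepest in grey matter, with a median of 80714 counts per region against 10761.5 to 46526.5 in the High AD donors. The margin therefore cannot be told apart from depth. As it also rests on 1 donor, it was not taken to exclude this explanation, and stage remains an untested explanation.

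The excess of probes higher in grey matter over those higher in white matter (75.9% of the calls) may come from the scaling, since upper-quartile scaling moved that share by 22.8 percentage points, to 53.1%. Scaling is not the only setting that moved it. With single regions as the unit, also scaled by TMM, the share was 16.1%. The median log2 fold change of all probes was 0.13 in that fit, 0.09 with upper-quartile scaling and 0.007 in the main fit. A shift over all probes thus went with both changes of the share. Depth stays open, because after thinning 60% of only 20 calls were higher in grey matter. The direction of the single probes named is not affected by this, and no biological explanation of the balance was tested.

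A candidate explanation for differences between plaque and plaque-free regions is a different share of white matter in the captured area. It was tested by an axis of probes chosen in the other donors, on which plaque-free grey matter of a donor is 0 and white matter is 1. Dense plaque regions lay at -0.297 ± 0.432 (SD, n = 9, exact sign-flip p = 0.043, adjusted 0.0645 over 3 tests), below grey matter in 6 of 9 donors. Leaving out 1 donor raised the exact sign-flip p above 0.05 for 6 of the 9 donors, to 0.0625 or 0.0859. The score moved most, to -0.179, without High AD donor 1 (exact sign-flip p = 0.0859). White matter plaque regions lay below plaque-free white matter in 7 of 8 donors (a difference of -0.252 ± 0.375, n = 8, exact sign-flip p = 0.0156, adjusted 0.0469). The difference was -0.123 without High AD donor 1 (exact sign-flip p = 0.0312). In plain log2 units dense plaque lay at -0.221 ± 0.271 and white matter plaque at -0.204 ± 0.215 (exact sign-flip p = 0.043 and 0.0156, unadjusted). A score on this axis cannot tell a different white matter share from a change of the same probes at plaques, so the share itself is not shown to differ. For sparse plaque the difference of -0.0974 ± 0.482 (n = 9; exact p = 0.598, 95% interval -0.422 to 0.171) left the question open, and its sign turned without High AD donor 1 (0.0323) and in plain log2 units (0.045).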

How the results depend on the processing

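The limit on single regions and the removal of the most abundant probes were chosen after the data had been seen. Apart from the ranges over left-out donors, counts of calls are given only where they moved by over 1.5 times. The median probe averaged 2.05 counts per region, so that depth and the filter on low counts limit which probes can be tested at all. Negative-control subtraction was not run because those probes are not identified. The cause of each change was not tested, except that thinning and leaving out donors test fewer probes or samples.

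With DESeq2, dense against sparse plaque, white matter plaque, High AD against Control grey matter, High AD against Low AD white matter and the interaction gave 0 calls, Low AD against Control gave 174 in grey and 436 in white matter, High AD against Control white matter gave 209 and High AD against Low AD dense plaque 22. Upper-quartile scaling gave 0 for dense against sparse plaque, 1 for white matter plaque and 3 for the interaction. Without a filter on low counts the calls were 2 in dense and 19 in sparse plaque against grey matter, 21 in dense against sparse plaque, 14 in white matter plaque, 41 and 36 in grey matter of High AD against Control and Low AD, 5 and 13 between stages in dense and sparse plaque, and 12 for the interaction. The stricter filter gave 0 for High AD against Control white matter and 321 for Low AD against Control white matter. With all regions kept, dense against sparse plaque gave 1. With regions under 10000 counts left out the calls were 1 and 47 in grey matter of High AD and Low AD against Control, 2 in High AD against Control white matter and 4 for the interaction.

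Without the donor as a block, white against grey matter gave 58 calls, and dense against sparse plaque, white matter plaque and the interaction 0. Donors of different stages that share a number are different people, and the numbers were not taken as pairs: no stage comparison had over 2 pairs correlated above 0.1, and the median pair ranged from -0.197 to 0.112. With the donor number as a block, Low AD against Control gave 37 in grey and 19 in white matter, and High AD against Control in grey and white matter and High AD against Low AD in white matter gave 0. The number as a block moved no other count by over 1.5 times. With plate as a block Low AD against Control gave 11 in grey and 9 in white matter, High AD against Low AD 6 in grey matter and 1 in dense plaque, and High AD against Control 0 in white matter.

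Single regions with the donor as a random block gave 442 calls in white against grey matter, 2 in dense plaque against grey matter, 0 in dense against sparse plaque, in white matter plaque and for the interaction, 29, 438 and 2 in grey matter (High AD with Control, Low AD with Control, High AD with Low AD), 461, 1194 and 66 in white matter in the same order, and 74 and 2 in dense and sparse plaque between stages. Low AD against Control had 419 higher and 19 lower in grey and 996 higher and 198 lower in white matter. High AD against Low AD had 5 higher and 61 lower in white matter and 5 higher and 69 lower in dense plaque. The median log2 fold change of all probes was 0.18, 0.07, -0.09 and -0.13 in that order. In High AD against Control white matter, 410 were higher and 51 lower at a median of -0.01. How far such shifts made the counts was not tested. Thinning gave 20 in white against grey matter, 0 in dense against sparse plaque, white matter plaque and the interaction, 1 and 11 in grey matter of High AD and Low AD against Control, and 0, 76 and 0 in white matter. With the limit on single regions the calls were 0 in dense against sparse plaque and the interaction, 1 in white matter plaque, High AD against Control grey matter and dense plaque between stages, 136 in Low AD against Control grey matter and 3 in High AD against Low AD white matter. Without the 20 most abundant probes, dense against sparse plaque gave 1 and High AD against Low AD grey matter 7.

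Leaving out 1 donor at a time gave 161 to 234 calls in white against grey matter and 0 in dense and in sparse plaque against grey matter. The range was 0 to 3 in dense against sparse plaque, 0 to 7 in white matter plaque, 4 to 38, 5 to 154 and 0 to 39 in grey matter, 0 to 199, 179 to 1022 and 0 to 64 in white matter (each High AD with Control, Low AD with Control, High AD with Low AD), 0 to 13 in dense plaque, 0 to 1 in sparse plaque and 0 to 36 for the interaction. Dense against sparse plaque lost its calls without Control donor 3 or Low AD donor 2 and kept 1 without High AD donor 4 or Low AD donor 3. White matter plaque gave 0 without Low AD donor 1, 1 without High AD donor 2 or 4 and 7 without High AD donor 1. The 4 named probes kept their direction in every alternative that tested them, and without the donor as a block RTS0027108 and RTS0026729 no longer passed (adjusted p = 0.192 and 0.154) at log2 fold changes of 1.30 and 1.12, against 1.35 and 1.16 with it.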

Other observations

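Over the 52 summed profiles of a donor and region type, the first principal component of the 500 most abundant probes held 40.3% of the variance, and 88.1% of it lay between donors, 70.7% between stages, 18.0% between plates and 3.04% between region types. The third component, with 9.19% of the variance, was the one in which region types accounted for the largest share of the first 4, at 33.2%, beside 34.3% between donors. The share between donors contains that between stages, since each donor belongs to 1 stage.

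Within white matter without plaque the first component (53.1% of the variance) ranged from -3.65 to 18.63 in the Control donors, from -10.14 to -4.61 in the Low AD donors and from -13.09 to -2.21 in the High AD donors. Within grey matter (38.0%) the ranges were -1.44 to 14.07, -9.14 to -4.33 and -6.54 to 5.38. The lowest Control score was that of Control donor 1 in both. That donor was the only Control donor on plate A. It was also the shallowest Control donor, with medians of 19352 counts per region in white and 10667 in grey matter. Donor, plate and depth cannot be told apart for its scores. Stage means were compared after these values had been seen, in 6 exact permutation tests. The smallest p was 0.0286, for Low AD against Control in grey matter (n = 4 and 4), the smallest that 4 against 4 donors can give, and after adjustment none was below 0.114. In grey matter each Low AD donor lay below each Control donor, and in white matter too.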
